A study of Mus musculus with 84 samples.

How the data were processed

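Allele-specific gene expression was measured by RNA sequencing in 84 samples. Of these, 68 were libraries from adult female F1 hybrids of reciprocal crosses between the mouse strains CastEiJ and C57BL/6J, taken from the arcuate nucleus of the hypothalamus (ARN, 18 libraries), the dorsal raphe nucleus of the brainstem (DRN, 18), liver (16) and muscle (16). Per the labels, F1i hybrids had a CastEiJ mother and F1r hybrids had a C57BL/6J mother, RNA was extracted with Trizol, and libraries were prepared from poly(A)-selected RNA with an Illumina kit. A further 9 samples made up 3 trios of wild-derived mice with hypothalamus RNA, and 7 samples of the parental strains were not analysed here. The labels do not say that libraries came from separate animals, so p-values measure the spread between these samples. The free-text descriptions of the muscle samples name the other cross than their titles and strain fields do. The titles and strain fields were used, and imprinted genes of known direction were examined as a check of the cross labels.

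The authors deposited raw read counts per gene for the CastEiJ and the C57BL/6J allele of each library, without normalization, 15499 genes per tissue table. For the wild trios the authors deposited counts of maternal and paternal reads and of SNPs for 7 genes, a log2 maternal over paternal ratio from the hybrids and its p-value, per the file headers. The aligner, SNP calls, genome build and strand setting are not given in the sources used here. All value columns used were matched to samples, with 0 left unmatched. Gene identifiers were matched to GENCODE M21 on GRCm38, which named 14969 genes and left 530 without a name or place, and coordinates are those of that annotation. Genes are called autosomal below if they are neither X-linked (530 genes) nor among 4 nuclear genes whose sequence matches mitochondrial genes over at least 100 bases at 90% identity or more (BLAST+ 2.17.0). That class includes identifiers without a known chromosome.

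Allele counts were tested with edgeR 4.0.16 (R 4.3.3) by glmQLFit with legacy=FALSE and glmQLFTest. The model had each library as a block, the strain of the allele and the parent of the allele, with 1 library size shared by both alleles and no TMM factor. The parent coefficient is the log2 ratio of the maternal over the paternal allele, and the strain coefficient that of the CastEiJ over the C57BL/6J allele. Total expression, the sum of both alleles, was compared between crosses with TMM normalization and is given as F1i over F1r. Differences of the parental effect between tissues were tested as contrasts in joint fits. Genes needed a mean of at least 10 allele-assigned reads per library and a Benjamini-Hochberg adjusted p under 0.05, and strain effects also an absolute log2 ratio of at least 1. Errors after ± are SD over libraries for shares and CPM (made here from the deposited counts) and standard errors for log2 values. Ratios of genes with almost no reads from 1 allele depend on the smallest counts, so shares are given for these. The X-linked share was compared between crosses by an exact 2-sided permutation test over 48620 (brain) or 12870 (body) assignments, and shared or nearby genes by Fisher's exact test. Fisher's test counts genes as independent, which genes of 1 cluster are not. Wild trio shares carry exact Clopper-Pearson 95% intervals and exact sign tests. Where no read of an allele was found, the upper limit is the share that 3 counts over all libraries of a cross would give. Intervals and limits cover counting error only.

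Depth ranged from 7.64 to 12.3 M (mega) allele-assigned reads per library in ARN, 4.80 to 12.7 M in DRN, 6.85 to 15.6 M in liver and 6.40 to 10.7 M in muscle. The fits were tested on simulated counts with 200 changed genes. The dispersion was set to 0.05 for totals and 0.01 for alleles in every tissue, not to the spread of each tissue. The recovered shares therefore do not compare the sensitivity of the real data between tissues. For the parental effect, changes of 0.25 on the log2 scale were recovered for 59.2% of changed genes in ARN, 58% in DRN, 64% in liver and 30% in muscle, and changes of 0.5 for 88%, 90%, 94% and 88%, with 12, 8, 10 and 7 false calls. For total expression between crosses, changes of 0.5 were recovered for 18%, 22%, 18% and 18% and changes of 1 for 94%, 100%, 98% and 92%. For the tissue contrasts, changes of 0.5 were recovered for 78.9% between ARN and DRN and 73.6% between liver and muscle.

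The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The lists were imprinted genes of known maternal, paternal or isoform- and tissue-dependent expression, the monoamine system, ARN feeding neuropeptides, DRN serotonin neurons, neighbouring hypothalamus, pituitary, choroid plexus and ependyma, hepatocytes, muscle fibres, erythroid cells, adipocytes, immune cells, oligodendrocytes, astrocytes, endothelium, immediate early genes, interferon response, MHC, hepatic drug metabolism, sterol and lipid synthesis, and X inactivation or escape. Counts adjusted over the list alone are given beside those over all genes. The imprinted lists come from general knowledge of the mouse, which can include work on these crosses, so they are not independent evidence. Named genes were the called genes of the lists, with priority to 12 classic imprinted genes, of which Snrpn and Ndn were not analysed here. To these were added the 8 unlisted genes with the largest parental ratio and at least 50 reads, the 5 most biased genes per strain with at least 200 reads and both alleles in every library, the 5 highest and 5 lowest genes between crosses with at least 50 reads, the 8 largest tissue contrasts with at least 50 reads in each tissue, which leaves out Grb10, and the wild trio genes. The values of 2 genes that the rule picked are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

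Alternatives were DESeq2 1.42.0, limma 3.58.1 on log2 ratios with a pseudocount of 0.5, the legacy edgeR fit, no filter or 50 reads, per-allele TMM factors, DESeq2 size factors, no library block, flow cell terms where labels give flow cells, a replicate block, thinning to 4.80 M reads, an adjusted p under 0.01, and leaving out each library. Leaving out X-linked and mitochondria-like genes, and a term for the pair of lanes (1 and 5, 2 and 6, 3 and 7), were added after seeing the data. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.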

Results

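Expression of the maternal and paternal allele was measured in 8-week-old female F1 hybrids of CastEiJ, a wild-derived inbred strain, and C57BL/6J, the common laboratory strain. F1i hybrids received the CastEiJ genome from the mother and F1r hybrids received it from the father, so that an effect of the parent can be separated from an effect of the strain. ARN and DRN were each represented by 9 F1i and 9 F1r libraries, liver and muscle by 8 and 8. Median depth was 11.3 M (mega) allele-assigned reads per library in ARN, 10.7 M in DRN, 12.7 M in liver and 7.32 M in muscle. Marker genes followed the dissected tissue. Tph2 and Slc6a4, the synthesis enzyme and transporter of serotonin, reached 533 ± 62.7 and 316 ± 40.1 CPM in DRN against 0.346 and 0.139 in ARN. Agrp, a feeding neuropeptide, stood at 14.0 ± 7.80 CPM in ARN and 0.0893 in DRN, while Acta1, skeletal muscle actin, reached 21103 ± 1839 CPM in muscle and Apoa1, a liver apolipoprotein, 30.8 CPM in liver.

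The first question was which genes depend on the parent that transmitted the allele. In ARN, Meg3, a maternally expressed noncoding RNA (chromosome 12, 109541001 to 109571726), carried 99.6% ± 0.279 maternal reads in F1i and 99.9% ± 0.0529 in F1r (n = 9 each). Peg3, a paternally expressed zinc finger gene (chromosome 7, 6703892 to 6730431), carried 0.0513% and 0.412% maternal reads, and Impact, a translation regulator (chromosome 18, 12955852 to 12992950), 0.426% and 2.30%. Grb10, a growth factor receptor adaptor (chromosome 11, 11930508 to 12038683), was paternal in ARN, with 3.71% ± 0.721 and 2.22% ± 0.557 maternal reads. Partial maternal bias was found for Ube3a, a ubiquitin ligase (71.7% ± 4.57 and 77.3% ± 2.64, log2 ratio 1.56 ± 0.05, adjusted p = 4.44e-23), and for Trappc9, a vesicle trafficking gene (65.8% ± 1.15 and 72.3% ± 0.848, 1.16 ± 0.02, adjusted p = 7.79e-35). Igf2, a fetal growth factor that is paternal in most tissues, was maternally biased in ARN at 69.6% ± 6.68 and 72.4% ± 7.88 (log2 ratio 1.27 ± 0.10, adjusted p = 1.27e-11).

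Across all ARN genes the parental effect passed the test for 402 of 13560 genes, 330 maternal and 72 paternal. X-linked genes made up 241 of these, 240 of them maternal, and mitochondria-like genes 3. Of the remaining 158 autosomal genes, 87 were maternal and 71 paternal. The X-linked genes of a library share its skew of the X chromosome, described below, so the 241 X-linked calls are not separate parental effects. The maternal imprinted list had 18 of 25 measured members biased to the mother and 1, the apoptosis regulator Bcl2l1, to the father at a log2 ratio of -0.59 ± 0.03 (19 and 1 adjusted over the list alone). The paternal list had 19 of 26 members biased to the father and 3 to the mother (19 and 3 adjusted over the list alone), namely Igf2, the antisense RNA Nespas with 0 paternal among 1792 reads in F1i and 1632 in F1r, which allows shares up to 0.167% and 0.184%, and Ddc, the aromatic amino acid decarboxylase of monoamine synthesis (0.82 ± 0.04). Nespas overlaps Gnas on the other strand, and as the strand setting of the counts is not given in the sources used here, its reads are uncertain in ARN and DRN. Of 10 genes listed as isoform- or tissue-dependent, 3 were maternal and 2 paternal, and they included the coatomer gene Copg2 at 84.9% and 85.3% maternal reads. These lists can rest in part on earlier work on the same crosses and are not independent evidence.

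Among genes on no imprinted list, the strongest paternal gene in ARN was Gm38393 (chromosome 7, 59974149 to 60005064), with 0.505% and 0.179% maternal reads. It overlaps Snrpn and Snhg14 of the Prader-Willi region, and its reads are uncertain. A230006K03Rik, a noncoding RNA of the same chromosome (61127996 to 61311721), carried 1.17% and 1.5% maternal reads. Identifiers without a name in the annotation used included ENSMUSG00000091793 and ENSMUSG00000091158 on the maternal side (99.5% and 99.1% maternal reads in F1i) and ENSMUSG00000078690 on the paternal side (0.431%). Most of the 112 unlisted autosomal genes showed small effects, with a median absolute log2 ratio of 0.22, 87 of them below 0.5 and 13 at 1 or more. Placement near imprinted genes was common, since 51 of 105 with a known position lay within 1 Mb of a listed imprinted gene (48.6%) against 2.74% of uncalled genes (odds ratio 33.6, Fisher's exact p = 3.96e-49, and 62.2 within 250 kb and 7.27 within 5 Mb). Neighbouring genes of 1 cluster are not independent, which this test does not account for here or in the other tissues. Without a library block the count of called genes in ARN was 143, and without X-linked and mitochondria-like genes it was 151.

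**Figure D1:**
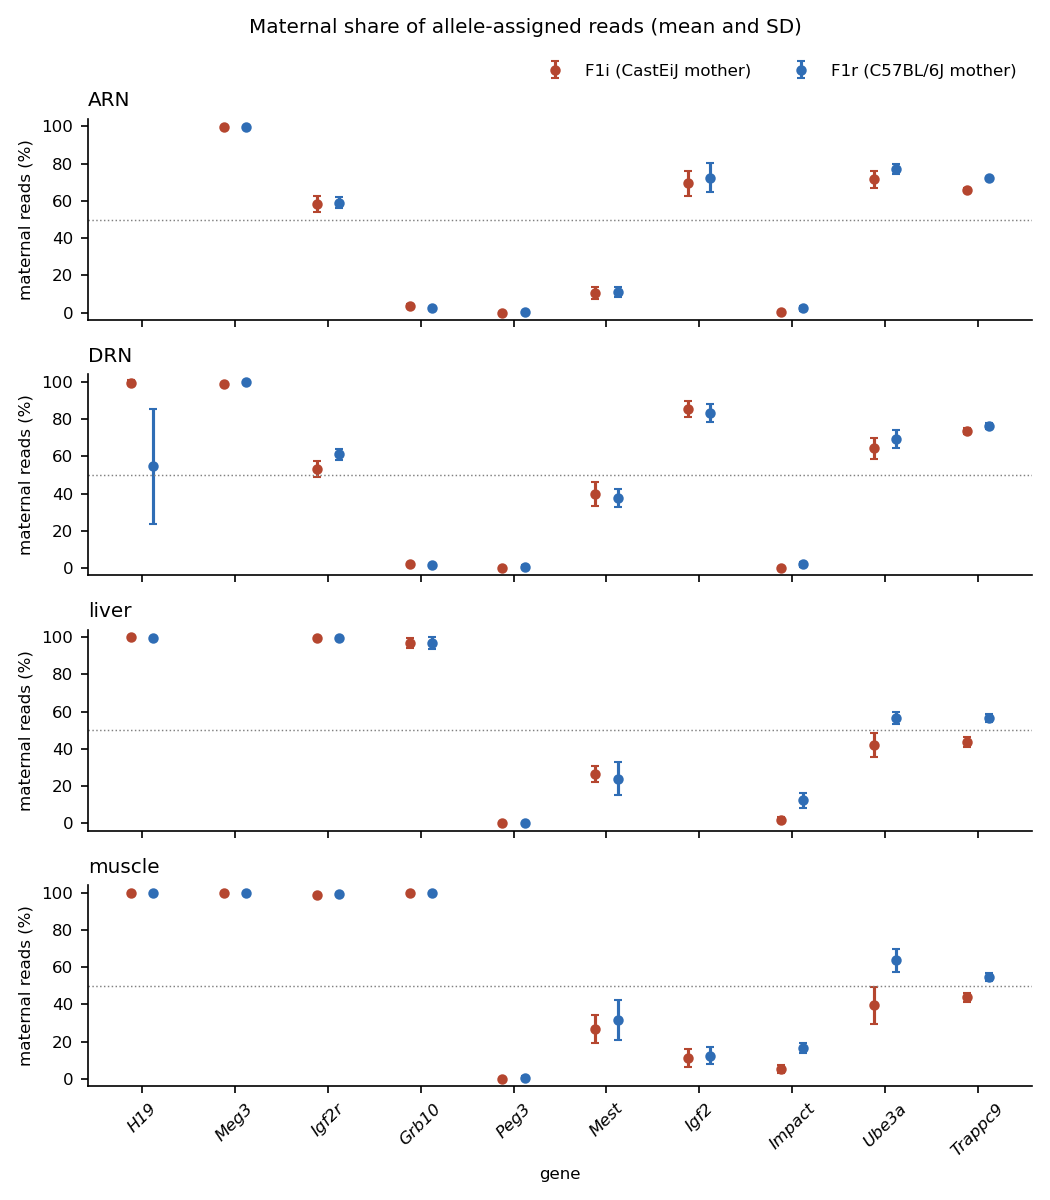
Maternal share of allele-assigned reads in percent for 10 imprinted genes (mean and SD over 9 libraries per cross in ARN and DRN and 8 in liver and muscle), by tissue and cross, with a dotted line at 50%. Igf2r and Grb10 sit at 58.1% and 3.71% in ARN F1i libraries and at 98.8% and 99.8% in muscle F1i libraries, and genes below the read minimum in a tissue have no point.

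In DRN the same classes of genes were found. Meg3 carried 99.1% and 99.9% maternal reads, Peg3 0.0624% and 0.542%, Impact 0.248% and 1.94%, and Grb10 1.95% and 1.76%. Igf2 was maternal at 85.3% ± 4.20 and 83.1% ± 4.94 (log2 ratio 2.37 ± 0.10), Trappc9 at 73.7% ± 1.51 and 76.0% ± 1.59, and Ube3a at 64.2% ± 5.88 and 69.3% ± 4.63 (1.02 ± 0.06, adjusted p = 2.21e-16). Mest, a paternally expressed hydrolase that overlaps Copg2, was only partly paternal (39.7% ± 6.30 and 37.5% ± 4.95 maternal reads, -0.63 ± 0.07, adjusted p = 2.26e-08). H19, a maternally expressed noncoding RNA, had few reads and carried 99.6% ± 1.33 maternal reads in F1i and 54.6% ± 30.9 in F1r. The test called 365 of 13418 genes, 307 maternal and 58 paternal, of which 244 were X-linked, 3 mitochondria-like and 118 autosomal. On the maternal list 16 of 26 members were maternal and 2 paternal, Bcl2l1 and the copper metabolism gene Commd1 (19 and 2 adjusted over the list alone). On the paternal list 20 of 26 were paternal and 3 maternal, again Igf2, Nespas and Ddc (20 and 3 adjusted over the list alone), and of 10 isoform- or tissue-dependent genes 1 was maternal and 2 paternal. Unlisted autosomal genes numbered 74, with a median absolute log2 ratio of 0.23, and 34 of 67 with a position lay within 1 Mb of a listed gene (odds ratio 34.8, Fisher's exact p = 9.59e-34, and 8.67 within 5 Mb). Both brain regions shared 43 unlisted genes, all in the same direction, where 0.634 would be shared by chance (Fisher's exact p = 4.18e-73). The DRN count was 144 with DESeq2, 180 with limma, 118 without a library block and 108 without X-linked and mitochondria-like genes.

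On the list of monoamine genes 4 of 14 measured members were maternal in ARN (5 maternal and 1 paternal adjusted over the list alone) and 4 of 22 in DRN (5 adjusted over the list alone). They were Ddc in both regions, Th, the tyrosine hydroxylase of dopamine synthesis, in ARN (53.5% and 52.0% maternal reads, log2 ratio 0.16 ± 0.03, adjusted p = 0.000268), the X-linked monoamine oxidases Maoa and Maob in both regions, and the X-linked serotonin receptor Htr2c in DRN. Of all X-linked genes 240 of 462 were maternal in ARN and 243 of 444 in DRN, and Ddc and Th are also on the imprinted lists. The effect on Ddc in DRN was small beside the strain effect, with 36.8% ± 1.03 maternal reads in F1i and 66.3% ± 1.04 in F1r (parental log2 ratio 0.10 ± 0.02, adjusted p = 3.84e-05). Maoa and Maob had log2 ratios of 0.37 ± 0.06 and 0.27 ± 0.07 in ARN and 0.27 ± 0.06 and 0.27 ± 0.05 in DRN. The DRN serotonin list had 1 called gene of 9 in DRN and 1 of 4 in ARN, Ddc in each. Ghrh, the growth hormone-releasing hormone, was the 1 of 17 feeding neuropeptides called in DRN (0.89 ± 0.23), and 0 of 20 were called in ARN by edgeR or DESeq2 (0 adjusted over the list alone, 3 at an unadjusted p under 0.05). Without a library block the calls of Th, Maoa, Maob, Htr2c and Ghrh, and that of Ddc in DRN, ended. With DESeq2 or limma those of Ghrh, Htr2c and, in DRN, Maoa ended, and that of Htr2c also with flow cell terms and without any of 7 single libraries.

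In liver fewer genes were called than in the other tissues. H19 carried 100% maternal reads in F1i (0 of 368 paternal, which allows up to 0.815%) and 99.8% in F1r, and Igf2r, the receptor that clears IGF2 (chromosome 17, 12682406 to 12769664, whose reads are uncertain beside the antisense Airn in the same place), 99.7% ± 0.248 and 99.8% ± 0.174. Grb10, paternal in brain, was maternal in liver at 97.0% ± 2.64 and 97.1% ± 3.23. Peg3 had 0 maternal among 1425 reads in F1i and 1888 in F1r, which allows shares up to 0.211% and 0.159%, and Impact had 1.97% ± 1.30 and 12.4% ± 3.93. Neither Ube3a (-0.02 ± 0.07, adjusted p = 0.99) nor Trappc9 (0.01 ± 0.04, adjusted p = 0.984) was called. In all, 32 of 11477 genes passed, 21 maternal and 11 paternal, with 3 X-linked, 3 mitochondria-like and 26 autosomal genes among them. The maternal list had 8 of 21 members maternal (9 maternal and 2 paternal adjusted over the list alone), the paternal list 8 of 14 paternal and 1, Ddc, maternal (8 and 3 adjusted over the list alone), and the isoform- and tissue-dependent list 1 of 10, Grb10. The 8 unlisted autosomal genes included the steroid hydroxylase Cyp17a1 (0.40 ± 0.07, adjusted p = 0.00464) and the anion transporter Slco1a1 (0.41 ± 0.09, adjusted p = 0.0372), both of which lost the call without a library block. The X-linked GTPase regulator Arhgap6 (0.78 ± 0.16, adjusted p = 0.0319) lost it there too, and Slco1a1 and Arhgap6 each lost it when any of 10 single libraries was left out and with the pair of lanes as a term. The liver count was 21 at a mean of 50 reads and 19 at equal depth.

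Muscle combined strong classic imprinting with many small effects. H19 carried 99.7% maternal reads in each cross, Meg3 99.8%, Grb10 99.8% and 99.9%, and Igf2r 98.8% ± 0.533 and 99.2% ± 0.572. Peg3 carried 0.0740% and 0.706%, Slc38a4, an amino acid transporter, 0.489% and 3.58%, and Igf2 11.3% ± 4.75 and 12.4% ± 4.66, the paternal direction opposite to that in brain. Ube3a (0.03 ± 0.11, adjusted p = 0.973) and Trappc9 (-0.04 ± 0.03, adjusted p = 0.724) were not called. The test called 177 of 10899 genes, 134 maternal and 43 paternal, of which 70 were X-linked, 3 mitochondria-like and 104 autosomal. The maternal list had 7 of 22 members maternal and 2 paternal, Bcl2l1 and Commd1 (9 and 2 adjusted over the list alone), the paternal list 13 of 16 paternal (13 adjusted over the list alone), and the isoform- and tissue-dependent list 5 of 11, all maternal. The 77 unlisted autosomal genes had a median absolute log2 ratio of 0.16. Of these, 25 also differed in total expression between the crosses, a larger share than the 928 of all 10899 genes tested. Whether the 2 effects are linked was not tested. Of the 77, 3 had an absolute log2 ratio of 1 or more. A smaller ratio was found for 6430548M08Rik, with 43.1% and 73.6% maternal reads (0.56 ± 0.06, adjusted p = 5.84e-08). The X-linked Pfkfb1, a regulator of glycolysis, had 15.1% and 93.0% (0.73 ± 0.14, adjusted p = 0.00239) and lost the call without a library block. Tnnt3, a fast troponin close to H19 and Igf2, was the 1 of 5 muscle fibre genes called, with 54.1% ± 0.312 and 48.9% ± 0.468 maternal reads (0.09 ± 0.01, adjusted p = 1.28e-13). Of the unlisted genes with a position, 8 of 72 lay within 1 Mb of a listed gene (11.1% against 2.94%, odds ratio 4.12, Fisher's exact p = 0.00135), but the odds ratio was 10.3 within 250 kb and 1.29 within 5 Mb (Fisher's exact p = 0.469). The muscle count was 77 with DESeq2, 99 with limma, 40 without a library block and 94 at an adjusted p under 0.01.

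**Figure D2:**
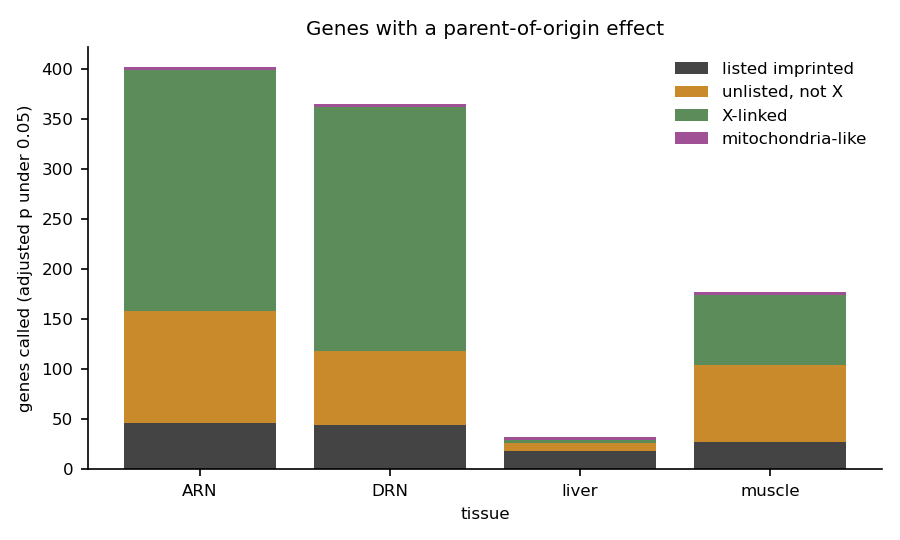
Number of genes with a parental effect (edgeR, adjusted p under 0.05) in each tissue, stacked by class: listed imprinted, unlisted and not X-linked, X-linked, and mitochondria-like. The totals are 402, 365, 32 and 177 genes in ARN, DRN, liver and muscle, and X-linked genes form the largest class in ARN and DRN. X-linked genes of a library share its skew of the X chromosome, so their calls are not separate effects.

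How strongly genes favoured a parent differed among the called autosomal genes. In ARN 30 genes (19%) had at least 90% of reads from the favoured parent in each cross, among them Meg3, Peg3 and Plagl1, a paternally expressed zinc finger gene. DRN had 31 such genes (26.3%), liver 10 (38.5%) and muscle 16 (15.4%). Of these, 19, 21, 10 and 14 were listed imprinted genes. The numbers were 38, 35, 12 and 21 at 80% and 25, 28, 10 and 16 at 95%.

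Direct tests of the tissue difference separated genes that were imprinted in some tissues. Between ARN and DRN, 37 of 13179 genes differed, 25 with a more maternal ratio in ARN and 12 in DRN, and 23 of them were listed imprinted genes. Dlk1, a paternally expressed Notch ligand, carried 0.110% and 0.309% maternal reads in ARN and 1.53% and 1.82% in DRN. Mest was far more paternal in ARN, with 10.4% and 11.2% maternal reads, than in DRN (difference -2.45 ± 0.12, adjusted p = 1.86e-22). Mest overlaps Copg2 and the strand setting of the counts is not given, so its reads are uncertain in both regions. More paternal in ARN were also the retrotransposon-derived Rtl1 (8.79% and 12.6% against 36.2% and 32.6%) and Begain, a postsynaptic protein of the same cluster (10.9% and 12.8% against 27.6% and 27.0%). Zdbf2 and Magel2 were more fully paternal in DRN, and Asb4, maternal in both, reached 93.8% and 92.9% in DRN and 82.2% and 87.6% in ARN.

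Liver and muscle differed for 17 of 10088 genes, 9 with a more maternal ratio in liver and 8 in muscle. Slc38a4 was biallelic in liver (52.7% and 48.9% maternal reads) and paternal in muscle (difference 6.27 ± 0.13, adjusted p = 2.43e-31). H13, a signal peptide peptidase, was maternal in both, at 77.2% and 76.7% in liver and 82.8% and 80.6% in muscle. At an adjusted p under 0.01, 8 genes remained past the threshold. Between brain and body, 68 of 9880 genes differed, 42 with a more maternal ratio in brain and 26 in body. Igf2r was almost completely maternal in liver and muscle and stood at 58.1% ± 4.26 and 59.0% ± 2.80 in ARN and 53.3% and 61.0% in DRN (difference -7.15 ± 0.09, adjusted p = 1.95e-80). Copg2, Trappc9 and Ago2, an Argonaute gene beside Trappc9, were maternal in brain and near 50% in body, where Copg2 had 48.3% and 50.7% in liver. Inpp5f, a phosphatase gene with a paternal brain transcript, was at 25.2% and 23.8% maternal reads in ARN and at 46.0% and 57.7% in liver.

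The X chromosome was skewed to the CastEiJ copy in every tissue, and more so when it came from the mother. In ARN the CastEiJ share of X-linked reads over 461 genes was 72.1% ± 5.31 in F1i and 64.2% ± 3.82 in F1r, a parental effect of 3.96 percentage points (exact permutation p = 0.00177, adjusted over 4 tissues 0.00708). In DRN it was 72.3% ± 4.64 and 65.9% ± 4.55 (3.23 points, exact permutation p = 0.0104, adjusted 0.0209), and in muscle 68.0% ± 5.50 and 58.7% ± 7.76 (4.66 points, exact permutation p = 0.0169, adjusted 0.0226). Liver had 83.3% ± 10.1 and 73.6% ± 9.79 (4.86 points, exact permutation p = 0.0726) and did not pass. Xist, the RNA made by the inactive X, went the opposite way, with CastEiJ shares of 29.0% and 36.7% in ARN (exact permutation p = 0.00317), 29.0% and 35.5% in DRN (exact permutation p = 0.0139) and 32.3% and 40.9% in muscle (exact permutation p = 0.0264). The Xist shares in liver, 14.1% and 23.5%, did not pass (exact permutation p = 0.0883). The X inactivation and escape list had 3 maternal genes and 1 paternal gene of 8 in ARN (5 and 1 adjusted over the list alone), 1 and 1 of 8 in DRN (4 and 2), and 2 and 1 of 8 in muscle (3 and 1), Xist being the paternal gene each time. In liver edgeR and DESeq2 called 0 of 8, with 3 at an unadjusted p under 0.05. Its member Utp14a was maternal in ARN, DRN and muscle, at log2 ratios of 0.35, 0.36 and 0.37, and lost the call in ARN and DRN at equal depth. Within flow cells the effect was 4.33, 5.93 and 1.62 points in ARN, 2.23, 5.93 and 1.33 points in DRN, where a further flow cell held F1r only, and -4.72, 11.8 and 4.95 points in liver. Autosomal CastEiJ shares were 49.9% and 50% in ARN and 50.2% and 50% in muscle, differences of -0.0765 and 0.183 points that also passed (exact permutation p = 0.00671 and 0.000155, the latter the smallest possible, adjusted 0.0134 and 0.000622).

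**Figure D3:**
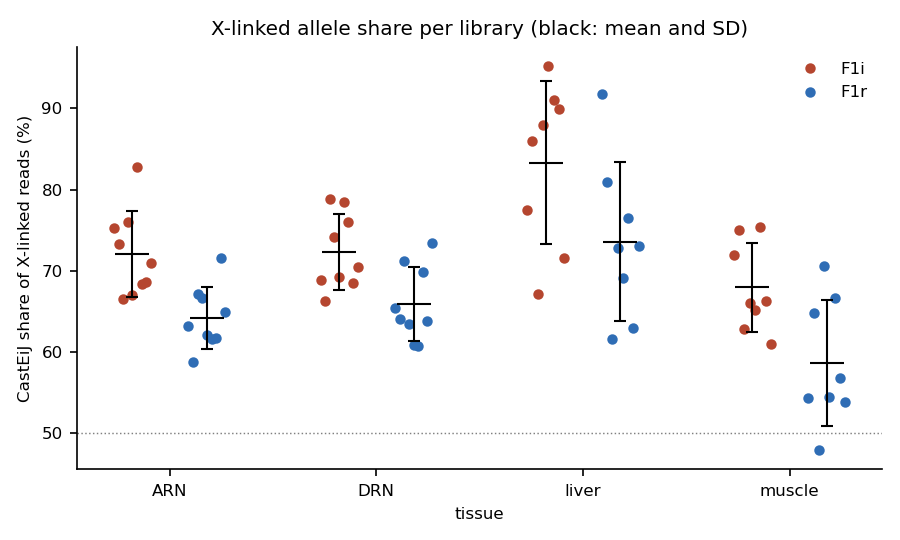
CastEiJ share of X-linked reads in percent for each library, by tissue and cross, with the mean and SD in black and a dotted line at 50%. F1i libraries average 72.1%, 72.3%, 83.3% and 68.0% in ARN, DRN, liver and muscle and F1r libraries 64.2%, 65.9%, 73.6% and 58.7%.

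Strain effects were more common than parental effects. In ARN 1031 genes passed with at least 2-fold bias, 767 to CastEiJ and 264 to C57BL/6J. DRN had 1074 (805 and 269), liver 1447 (951 and 496) and muscle 1041 (629 and 412). Of these, 710 in ARN, 703 in DRN, 1154 in liver and 940 in muscle were autosomal. X-linked genes share the skew of the X chromosome to CastEiJ, so their calls are not separate strain effects of each gene. The most biased brain genes were Rps12 and Rpl23a, ribosomal protein genes with CastEiJ shares of 99.8% and 98.9% in ARN F1i libraries, and Rps19 and Gapdh, a ribosomal protein gene and a glycolytic enzyme gene, with 1.61% and 4.37%. These genes have near-identical copies elsewhere, and their counts are uncertain. In liver Ces2h, a carboxylesterase, had CastEiJ shares of 99.6% in each cross and Serpina3c, a protease inhibitor, 99.3% and 99.0%, while the kinase gene Camk1d had 1.25% and 1.30% and the amino acid transporter Slc3a1 3.25% and 3.10%. In muscle the signalling gene Gng5, whose count is uncertain since a processed pseudogene matches its transcript, had 97.9% and 98%, Dkk3, a secreted glycoprotein gene, 1.47% and 1.60%, and Gapdh 1.03% and 0.996%. The MHC list had 1 CastEiJ-biased and 2 C57BL/6J-biased genes of 8 in ARN (1 and 2 adjusted over the list alone), with H2-Ab1 at 90.3% and 90.8% and H2-D1 at 20.8% and 19.5%. On the hepatic drug metabolism list 1 gene was biased to CastEiJ and 5 to C57BL/6J of 15 in liver (1 and 5 adjusted over the list alone), among them the glutathione transferase Gstm1 at 8.19% and 8.41% and the fatty acid hydroxylase Cyp4a14 at 21.0% and 15.7%. Members of these gene families share sequence, and their counts are uncertain. At a mean of 50 reads the counts were 662 in ARN, 676 in DRN and 596 in muscle.

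Total expression differed most between the crosses in muscle. Peg3 stood at 541 ± 127 CPM in F1i and 123 ± 25.6 in F1r (log2 2.17 ± 0.14, adjusted p = 2.08e-09), and among other imprinted genes Airn (1.11 ± 0.11, uncertain for its overlap with Igf2r) and Cdkn1c, a cell cycle inhibitor (0.56, adjusted p = 0.0101), were higher in F1i and Zim1, beside Peg3, was lower (-1.26 ± 0.21, adjusted p = 0.00199). Peg3 was read almost only from the paternal allele, which is that of C57BL/6J in F1i and that of CastEiJ in F1r. For such genes a strain difference of the expressed allele cannot be told apart from an effect of the cross. On the maternal list 4 of 22 genes were higher in F1i and 1 lower (5 and 2 adjusted over the list alone), on the paternal list 3 of 16 higher and 1 lower (3 and 1 adjusted over the list alone), and on the isoform- and tissue-dependent list 1 of 11 in each direction. Lower in F1i were also Cish, a cytokine signalling inhibitor (4.80 against 21.9 CPM, -2.05 ± 0.37), Stc2, a secreted glycohormone (25.1 against 72.4), Dusp7, a phosphatase (30.4 against 75.8), Arrdc2 (211 against 518) and Ddit4, a stress-induced mTOR inhibitor (12.5 against 30.0). In all 928 genes differed, 544 higher in F1i and 384 higher in F1r (904 autosomal, 532 and 372), with a median absolute log2 change of 0.44 and 41 genes at 1 or more. Markers of other cell types moved with the cross. The immune list had 5 of 7 genes higher in F1i (6 adjusted over the list alone), with Ptprc, the leukocyte common antigen, at 0.69 and Lyz2, lysozyme, at 65.8 against 48.4 CPM (0.48 ± 0.13, adjusted p = 0.0307). The endothelial list had 3 of 6 higher (5 higher and 1 lower adjusted over the list alone), with Cdh5, VE-cadherin, at 0.30 ± 0.08 and the angiopoietin receptor Tek at 0.50 ± 0.09. Both measured globin genes were higher (2 of 2, and 2 adjusted over the list alone), Hbb-bs at 0.72. Also higher were the fat cell gene Fabp4, the 1 of 4 adipocyte genes called (1 adjusted over the list alone), the myelin gene Mbp, the 1 of 4 oligodendrocyte genes called (4 adjusted over the list alone), B2m, the 1 of 9 MHC genes called (2 adjusted over the list alone), and Ifi27l2a, the 1 of 2 interferon genes called (1 adjusted over the list alone). Lower were Nr4a1, the 1 of 7 immediate early genes called (2 higher and 1 lower adjusted over the list alone), Lss, the 1 of 12 sterol genes called (1 adjusted over the list alone), the water channel Aqp4, the 1 of 4 astrocyte genes called (1 higher and 1 lower adjusted over the list alone), Esr1, the estrogen receptor, and Glul, glutamine synthetase (-0.92 ± 0.16, adjusted p = 0.00316). Of 5 muscle fibre genes, edgeR and DESeq2 called 0 (1 adjusted over the list alone, 1 at an unadjusted p under 0.05). Leaving out single libraries moved the count between 492 and 1798, and the calls of Ptprc and Lyz2 ended without any of 8 and 9 libraries.

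**Figure D4:**
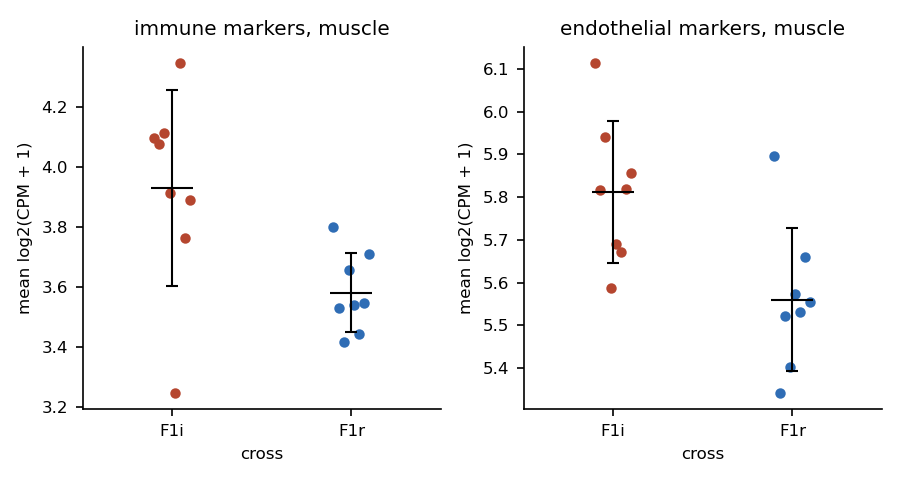
Mean log2(CPM + 1) of the immune and the endothelial markers in each of the 16 muscle libraries, by cross, with the mean and SD in black. The immune level is lowest in F1i replicate 5 at 3.25 and highest in F1i replicate 6 at 4.34, and the endothelial level is highest in F1i replicate 1 at 6.11.

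In ARN 157 genes differed in total expression, 67 higher in F1i and 90 higher in F1r (148 autosomal, 59 and 89). Trh, thyrotropin-releasing hormone, was lower in F1i (57.4 ± 9.40 against 99.3 ± 7.87 CPM, -0.77 ± 0.08, adjusted p = 6.22e-06), and Tac2, a neuropeptide of the neurokinin family, was higher (204 against 151 CPM, 0.46 ± 0.10, adjusted p = 0.029), so that 2 feeding neuropeptide genes rose and 1 fell of 20 (5 and 1 adjusted over the list alone). Of the neighbouring hypothalamus list, 1 of 6 genes changed, Hdc, the histamine synthesis enzyme (-0.56 ± 0.13, adjusted p = 0.0284, and 1 adjusted over the list alone). The ependymal markers Tmem212 (10.9 ± 1.76 against 20.4 ± 1.44 CPM, -0.88 ± 0.09) and Ccdc153 (28.6 against 47.0) were lower in F1i, 2 of 9 on their list (2 adjusted over the list alone). The myelin gene Cnp, the 1 of 7 oligodendrocyte genes called (7 lower adjusted over the list alone), and Gfap, the 1 of 6 astrocyte genes called (707 against 896 CPM, -0.32 ± 0.07, and 1 adjusted over the list alone), were also lower. Flt1 was the 1 of 6 endothelial genes called and was higher, Acaca the 1 of 12 sterol and lipid genes, also higher, and H2-Ab1 the 1 of 8 MHC genes, lower. Neither edgeR nor DESeq2 called any of 2 pituitary, 7 immune or 3 hepatocyte markers (1, 0 and 1 adjusted over the list alone, and 1, 0 and 1 at an unadjusted p under 0.05). Gypc, an erythrocyte membrane gene, was higher (6.94 ± 1.80 against 3.28 ± 0.988 CPM, adjusted p = 0.000976) and Lrat, a retinol esterification enzyme, lower (30.7 ± 22.2 against 78.5 ± 22.8 CPM, adjusted p = 0.0108). Without F1i replicate 8 the count was 94, without F1r replicates 2, 4 or 5 it was 101, 103 or 100, and DESeq2 gave 327. Another division of the libraries, drawn without regard to the cross but following it in part, called more genes (2098). All ARN libraries of F1r were sequenced in lanes 1 to 3 and all of F1i in lanes 5 to 7, so lane and cross cannot be told apart, and with the pair of lanes (1 and 5, 2 and 6, 3 and 7) as a term 243 genes were called, the 157 among them.

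DRN had 16 genes that differed, 14 higher in F1i and 2 higher in F1r, of which 4 were mitochondria-like and 2 X-linked, all higher in F1i, and 10 autosomal (8 and 2). Plagl1 was higher in F1i (54.1 ± 8.16 against 34.7 ± 3.63 CPM, 0.65 ± 0.08, adjusted p = 0.000142), and Ube3a (24.2 ± 1.76 against 35.5 ± 3.64 CPM, -0.54 ± 0.06, adjusted p = 2.25e-05) and the synaptic gene Cplx1 (402 against 491 CPM, -0.28 ± 0.06, adjusted p = 0.0452) were lower, Cplx1 losing its call without any of 14 single libraries. Plagl1 was read almost only from the paternal allele, so the strain of that allele changes with the cross. Of 7 oligodendrocyte and 2 erythroid markers in DRN, edgeR and DESeq2 called 0 over all genes, but 3 and 2 passed adjusted over the list alone (4 and 2 at an unadjusted p under 0.05), the oligodendrocyte genes lower in F1i (median log2 of the list -0.20) and the erythroid genes higher (0.42). Liver had 18, 9 in each direction, of which 4 were mitochondria-like and 1 X-linked, all higher in F1i, and 13 autosomal (4 higher in F1i and 9 in F1r). Slco1a1 (358 ± 89.9 against 680 ± 107 CPM, -0.92 ± 0.15, adjusted p = 0.0085) and Depp1 (122 against 254 CPM) were lower in F1i, and the sulfotransferase Sult2a6 (17.9 ± 8.47 against 4.70 ± 2.84 CPM, adjusted p = 0.0378) was higher, a call that ended without any of 6 single libraries and with the pair of lanes as a term. In liver, edgeR and DESeq2 called 0 of 11 hepatocyte, 0 of 15 drug metabolism and 0 of 6 interferon genes between crosses (0, 1 and 3 adjusted over the list alone, and 1, 3 and 4 at an unadjusted p under 0.05). Liver libraries of F1i were in lanes 1 to 3 apart from 1 in lane 6. Those of F1r were in lanes 5 to 7 apart from 1 in lane 2, so lane and cross were almost confounded there too. The counts were 56 in DRN and 203 in liver with DESeq2, and single libraries moved them as well, DRN to 27 without F1i replicate 3 and 29 without F1r replicate 4, liver to 111 without F1i replicate 7, 95 without F1r replicate 4, 29 without F1r replicate 6, 10 without F1i replicate 4, and 9 without F1r replicates 1 or 5. DRN libraries of F1i were in lanes 1 to 3 and those of F1r in lanes 5 to 8, and with the pair of lanes as a term 45 genes were called, the 16 among them. Same-numbered DRN libraries of both crosses shared a flow cell and lane pair for 8 of 9 numbers, and with a term for the number 105 genes were called.

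Nuclear copies of mitochondrial genes were read almost only in F1i. Gm13340 (chromosome 2, 22588103 to 22589647), 97.6% identical to mt-Co1, stood at 8475 ± 521 CPM in ARN F1i libraries and 0.926 ± 0.316 in F1r. In muscle it stood at 20050 ± 2652 and 21.5 ± 7.47, and Gm13341, Gm13339 and Gm11410 did likewise, at 10820, 1868 and 6511 CPM in F1i. In F1i at least 99.96% of their reads carried the CastEiJ allele, and together they took 1.33% of F1i reads in ARN, 1.83% in DRN, 2.53% in liver and 3.92% in muscle.

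The wild-derived trios asked whether the maternal bias of 7 genes holds outside the inbred crosses. In the 3 daughters, Herc3, a ubiquitin ligase (chromosome 6, 58831465 to 58920398), had 78.2% ± 4.42 maternal reads (SD, n = 3), Asb4, an ankyrin repeat gene (chromosome 6, 5383386 to 5433022), 91.1% ± 6.96, and Trappc9 78.5% ± 3.53. Ltv1, a ribosome assembly factor, had 71.5% ± 23.9 and Phactr2, a phosphatase and actin regulator beside it, 74.8% ± 21.3. Cobl, an actin nucleator, had 57.5% ± 7.07. Igf2r had 48.2% ± 13.2 as a mean over daughters with 1132, 24 and 41 reads, and 59.2% of the summed reads. The share was above 50% in all 3 daughters for Ltv1, Herc3, Asb4, Trappc9 and Phactr2, in 2 for Cobl and in 1 for Igf2r, and the smallest p that 3 trios allow in a 2-sided exact sign test is 0.25. In trio 1, Ltv1 had 80 maternal reads to 1 paternal and Phactr2 82 to 1, each on 1 SNP, while Trappc9 had 873 to 258 on 6 SNPs (77.2%, exact interval 74.6% to 79.6%). ARN hybrids had log2 ratios of 1.25 ± 0.02 for Herc3 and 2.51 ± 0.02 for Asb4, and the authors' deposited table lists 1.24 and 2.51.

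**Figure D5:**
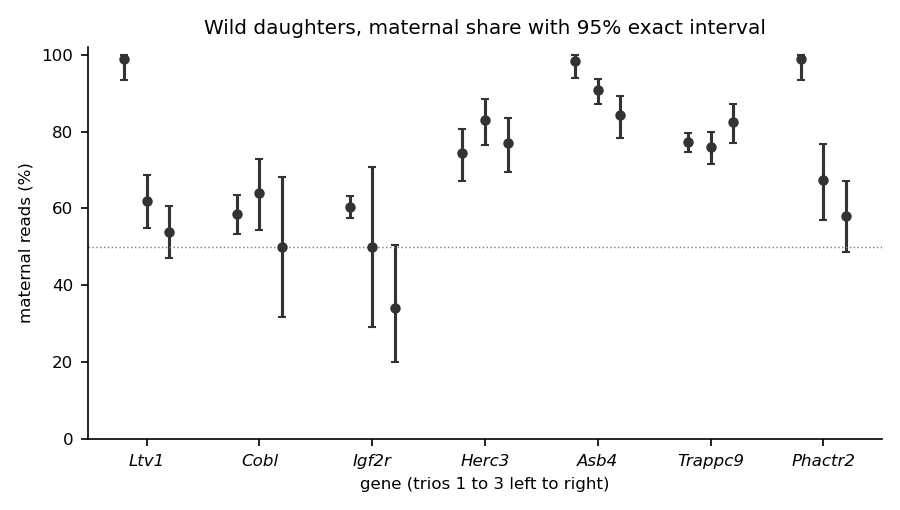
Maternal share of reads in percent for 7 genes in the 3 wild-derived daughters (trios 1 to 3 from left to right), with exact 95% intervals and a dotted line at 50%. Herc3, Asb4 and Trappc9 lie above 50% in all 3 daughters with intervals that exclude it, and Igf2r ranges from 60.3% to 34.1%.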

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

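The tests on the mitochondria-like genes were chosen only after the result was seen. Parental effects differed between tissues for 3 sets of genes. Between ARN and DRN 37 genes differed and between liver and muscle 17, and the highest of the other 21 splits of the libraries called 1 and 0. Those splits mixed libraries of both tissues, which also differ in expression and strain ratios. Low counts there cannot exclude chance for the 37 or 17 genes. Between brain and body 68 differed and the highest other split called 0, but the 8 splits mixed tissues as well and are too few for a share under 0.05. Among genes with at least 50 reads in each tissue, the log2 ratio of maternal over paternal reads differed between ARN and DRN by -3.15 for Dlk1, 2.69 for Zdbf2, -2.45 for Mest, 2.29 for Magel2, -2.12 for Rtl1, -1.52 for Begain, -1.30 for Asb4 and 2.00 for ENSMUSG00000087490. Between liver and muscle it differed by 6.27 for Slc38a4, 1.93 for Igf2r, -0.94 for Impact, -0.52 for 6430548M08Rik, -0.45 for the adhesion gene Vcam1, -0.42 for H13, 0.40 for the protease gene Ctsh and -0.82 for a gene with no name in the annotation used. Vcam1 lost its call with limma and without X-linked and mitochondria-like genes. Between brain and body it differed by -7.15 for Igf2r, -3.22 for Impact, 2.49 for Copg2, -1.90 for Inpp5f, 1.53 for Ago2, 1.39 for Trappc9, 3.62 for Gm11410 and 1.88 for Gm13339. Maternal reads were few for Dlk1 in ARN (0.110% and 0.309%) and Impact in liver F1i (1.97%), and Gm11410 and Gm13339 stood at only 0.223 to 7.10 CPM in F1r, so these differences rest on small counts.

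Among the depths, F1i replicate 8 of muscle stood apart, with 10.7 M (mega) allele-assigned reads against 6.40 to 8.28 M in the other 7 F1i libraries. It was the 1 such library in 36 groups tested, where chance alone gives about 1 in 20.

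The differences of Gm11410 and Gm13339 belong to a wider pattern, the nuclear copies of mitochondrial genes that were read as maternal CastEiJ. If these copies were expressed from the maternal chromosome of both strains, F1r libraries would carry them as well, but the highest F1r level over 4 copies and 4 tissues was 0.274% of the F1i level, which argues against that. The same value is what reads from the maternal CastEiJ mitochondrial genome, placed on a nuclear copy, would give, and this stays a candidate explanation. Expression of the CastEiJ copy alone, and only from the mother, stays open and was not tested.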

How the results depend on the processing

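The runs without X-linked and mitochondria-like genes and with lane pairs were chosen after the data were seen. Parental counts moved by more than 1.5 times without a library block (ARN 143, DRN 118, muscle 40), with DESeq2 (DRN 144, muscle 77), with limma (DRN 180, muscle 99), without X-linked and mitochondria-like genes (ARN 151, DRN 108, both by construction, since most calls are X-linked), in liver at a mean of 50 reads (21) and at equal depth (19), and in muscle at an adjusted p under 0.01 (94). Strain counts moved at a mean of 50 reads (ARN 662, DRN 676, muscle 596, where fewer genes are tested), without the size rule (9065, 8992, 7714 and 7318) and in muscle with no filter (1620). Counts of total expression moved with DESeq2 (ARN 327, DRN 56, liver 203) and with the pair of lanes as a term (ARN 243, DRN 45), the liver and muscle contrast at an adjusted p under 0.01 (8), and the odds ratio near listed genes within 5 Mb (33.6 to 7.27 in ARN, 34.8 to 8.67 in DRN, 24.2 to 5.35 in liver with adjusted p = 0.0593 over tissues, and 4.12 to 1.29 in muscle) and within 250 kb (62.2 in ARN, 42.3 in liver, 10.3 in muscle). The fit without a library block ignores that both alleles of a gene come from 1 library, so its counts are those of an unpaired comparison. Other than by construction, the cause was not tested. Apart from the replicate block and left-out libraries, other alternatives left the counts within 1.5 times.

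Replicate numbers were not taken to pair the samples, since not every pair correlated, although same-numbered libraries shared a flow cell and lane pair for 9 of 9 numbers in ARN and 8 of 9 in DRN. Deviations of same-numbered libraries correlated above 0.1 in 4 of 9 pairs in ARN, 6 of 9 in DRN, 3 of 8 in liver and 1 of 8 in muscle, and 2 of 18, 5 of 18, 3 of 16 and 1 of 16 libraries correlated best with their own number. In DRN the mean correlation was 0.241 for same-numbered and -0.0267 for other pairs. With the replicate block the parental counts were 383, 362, 32 and 268, those of total expression 183, 105, 23 and 465, and the contrasts 35, 13 and 56, of which 268, 105 and 465 moved by more than 1.5 times.

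Leaving out single libraries gave 330 to 460 parental genes in ARN, 294 to 407 in DRN, 24 to 37 in liver and 127 to 265 in muscle. Total expression ranged from 94 to 163 in ARN (94 without F1i replicate 8, and 101, 103 and 100 without F1r replicates 2, 4 and 5), 12 to 29 in DRN (27 without F1i replicate 3, 29 without F1r replicate 4), 9 to 111 in liver (10 and 111 without F1i replicates 4 and 7, and 9, 95, 9 and 29 without F1r replicates 1, 4, 5 and 6) and 492 to 1798 in muscle (574, 497, 1798, 586, 565 and 1625 without F1i replicates 1, 3, 4, 6, 7 and 8, and 492, 552, 497 and 615 without F1r replicates 2, 3, 6 and 7). The X-linked effect ranged from 3.29 to 4.42 points in ARN, 2.82 to 3.70 in DRN, 4.00 to 6.15 in liver and 3.89 to 5.51 in muscle, and in liver it passed without F1i replicate 3 (6.01, exact permutation p = 0.0277), F1i replicate 8 (5.70, p = 0.0429) or F1r replicate 1 (6.15, p = 0.0219). Of the 7 wild genes 6 averaged above 50%, and 6 to 7 without a trio, Igf2r rising to 55.2% without trio 3.

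Of 134 named parental genes, 121 kept their side of the threshold and direction in every leave-one-out fit, as did 55 of 86 named between crosses, and 101 and 42 did so under every other alternative. Only uncalled ratios changed sign, with leave-one-out ranges of -0.0587 to 0.0191 for Ube3a, -0.00338 to 0.0260 for Trappc9 and -0.0513 to 0.000306 for Copg2 in liver and -0.0226 to 0.0717 for Ube3a in muscle. Ube3a in liver was 0.0191 without F1i replicate 3, 0.00577 without F1i replicate 8 and 0.000324 without F1r replicate 2, Trappc9 was -0.00338 without F1i replicate 7 and Copg2 0.000306 without F1r replicate 2, and Ube3a in muscle was -0.00874 at equal depth and -0.0226, -0.00342 and -0.0197 without F1i replicate 6 and F1r replicates 1 and 8. In counts simulated at these depths, with a dispersion of 0.05 for totals and 0.01 for alleles in every tissue, parental changes of 0.25 were recovered for 30% of genes in muscle and 58% to 64% elsewhere, and cross changes of 0.5 for 18% to 22%. The real spread of each tissue was not simulated. With libraries thinned to equal depth, parental counts were 314, 283, 19 and 166, lower in each tissue. Total expression was not tested at other depths.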

Other observations

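The tests on pseudogenes, on random and matched gene lists in muscle and on the libraries and lanes behind the other splits were chosen only after the results were seen. In muscle 7 of 20 clock genes and 9 of 20 genes that respond to glucocorticoids differed between the crosses, against 928 of all 10899 genes tested. Both lists include genes already seen among the top muscle genes, so these counts are not independent of the result. Of the members not seen before, 4 of 17 and 5 of 15 differed. Per1 stood at 49.6 ± 15.1 CPM in F1i and 87.4 ± 19.6 in F1r (-0.79 ± 0.16, adjusted p = 0.0071), Per2 at 39.2 ± 10.6 and 83.7 ± 31.3 (-1.07 ± 0.24) and Nr1d1, a repressor of the clock, at 210 ± 37.8 and 101 ± 78.6 (1.11 ± 0.30, adjusted p = 0.0291). Of the glucocorticoid genes, Tsc22d3 stood at 124 ± 35.5 and 183 ± 25.3 CPM (-0.53 ± 0.14), Foxo3 at 101 ± 13.5 and 130 ± 15.3 and Pik3r1, a subunit of phosphoinositide kinase, at 24.0 ± 5.63 and 46.9 ± 12.5 (-0.93 ± 0.17, adjusted p = 0.00316). These genes fall outside the rule and were chosen after their values were seen.

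Some unlisted parental genes recurred across tissues. ARN and muscle shared 8, all in the same direction, where 0.595 would be shared by chance (Fisher's exact p = 1.22e-07), and DRN and muscle shared 5 (0.367 by chance, Fisher's exact p = 3.05e-05). Stx16, a vesicle fusion gene near Gnas, and Fuca2, a fucosidase gene near Plagl1, were among both sets, and Ctsh was among the first, all chosen here after their values were seen. Liver had 4 called unlisted genes that were tested in each other tissue. It shared 2 with ARN, 1 of them in the same direction, and 1 each with DRN and muscle.

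The cross difference of 928 genes in muscle may have several sources. The labels give no flow cell or lane for muscle libraries, so a batch that follows the cross cannot be examined. A different share of immune and endothelial cells cannot be told apart from the cross, since with both marker levels as terms 1.51% of called genes stayed called (median absolute log2 0.44 before and 0.26 after, with a standard error of 0.11 and 0.14), but 19 of 100 random list pairs kept as few and the terms vary with the cross. A different time of day at collection stays open, with an odds ratio of 3.32 for clock genes whose values had not been seen before (4 of 17 called, Fisher's exact p = 0.0508, matched random lists p = 0.0703). Different glucocorticoid exposure is in line with an odds ratio of 5.40 (5 of 15 called, Fisher's exact p = 0.00645, matched random lists p = 0.0064), with 4 of the 5 higher in F1r and Bcl6 higher in F1i. A biological effect of the cross stays open and untested beside these. For genes read almost only from 1 parent, a strain difference of the expressed allele cannot be told apart from the cross. Of 16 autosomal parental genes with at least 90% of reads from 1 parent in each cross, 4 differed, against 900 of 10571 others.

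Strongly strain-biased genes, such as Ndufs5, Rps19, Gapdh and Rpl23a, may reflect reads shared with processed pseudogenes. Copies were found for 6 of 9 such genes in ARN (66.7% against 24.3% of other genes, odds ratio 6.22, Fisher's exact p = 0.00874), 6 of 9 in DRN (6.23, p = 0.00866 by the exact test) and 12 of 22 in muscle (3.10, exact p = 0.00845), but in liver for 9 of 42 (0.756, exact p = 0.599). The 6 genes were the same in ARN and DRN and were among the 9 of liver, so the tissues are not separate results. The explanation cannot be told apart from cis-regulatory differences between the strains, which were not tested.

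Other splits of the same libraries bear on the counts. For parental effects chance can be excluded in each tissue, since 1 of 40 splits, the real one, reached 402, 365, 32 or 177 genes and the highest other split called 0 in ARN and DRN and 1 in liver and muscle. For strain effects the other splits called 0 genes against 1031, 1074, 1447 and 1041. They exchanged both alleles within random libraries, which turns a strain bias into spread and lowers its mean ratio. Low counts there cannot exclude chance for these genes. For total expression chance can be excluded in muscle (928 against 140, and 904 against 139 among autosomal genes). The lowest autosomal count in muscle with 1 library left out was 474, without F1r replicate 2. In liver 1 of 100 splits was as large, so chance can be excluded with all libraries in (18 against 7, and 13 against 7 among autosomal genes). That rests on single libraries, since without F1i replicate 4 the liver count was 10 and without F1r replicates 1 or 5 it was 9, of which 6, 4 and 4 were autosomal, fewer than the 7 of the other split, while it rose to 111, 95 and 29 without F1i replicate 7 and F1r replicates 4 and 6. In ARN (157) and DRN (16) 2 of 100 splits were as large, the highest other split calling 2098 and 40 genes. In both regions that split put replicates 1, 4 and 7 of both crosses on 1 side and replicates 2, 8 and 9 on the other. It divided replicates 3, 5 and 6 by cross, with F1i beside replicates 1, 4 and 7, so it followed the cross in part. It put all 6 libraries of lanes 1 and 5 on 1 side, with 1 library of lanes 2 and 6 and 2 of lanes 3 and 7, so it points to a structure of the libraries that follows the lanes, as the replicate numbers do. With the pair of lanes as a term the counts were 243 and 45, with the 157 and 16 genes among them, but each lane held 1 cross, so a difference between the lanes of either cross stays open.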
